A study of Homo sapiens
Mus musculus and Homo sapiens with 12 samples.

How the data were processed

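PolyA RNA was sequenced from 12 samples of a cell fusion experiment. Heterokaryons of D3 mouse embryonic stem cells and MRC5 human fibroblasts were collected 1, 2 and 3 days after fusion, with 2 samples per day. Controls were 2 co-cultures of the same cell types without fusion, 3 samples of unfused fibroblasts and 1 homokaryon sample, in which fibroblasts were fused with each other. The labels do not say whether replicates were separate cultures, so all p-values measure only the spread between these samples.

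The deposited tables list 1 value per RefSeq transcript accession. The human values of 11 of the 12 deposited tables were taken to be in a unit of the RPKM form, computed per transcript length and library. Value times transcript length clustered loosely near multiples of 1 step per library. That step was the best of many candidates and was not tested against values without a step, so the unit is an inference. RPKM, FPKM and TPM share this form, and the deposited values do not tell them apart; they are called RPKM here. The table of unfused fibroblast replicate 3 holds a signal in a unit the authors do not state, and none of its 8070 accessions is in the human RefSeq table. In the table of replicate 1, 12043 of 17527 values lie outside the human table in the same form of 2 decimals; their unit is not known either, and they were not used here. The processing notes name the genome builds hg19 and mm10, and the aligner is not given in the sources used here. Only human transcripts were analysed; mouse transcripts were not analysed here.

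The 11 other tables each hold exactly 10000 distinct values, list no value of 0 and run in accession order to an end that differs between libraries. Up to its end, a human transcript missing from a table was taken as 0; past the end it was taken as not covered, never as 0. Transcripts were joined to genes with the human RefSeq table, and 112 accessions that this table no longer holds were named with an older annotation table that links them to the same gene. A gene's value is the sum of its coding transcripts, and a gene entered a comparison only where every library of both groups covered all of its coding accessions. Values of isoforms are a division of reads between similar transcripts: of 2906 genes at 1 or more in the first co-culture library, 972 have more than 1 transcript and 364 of these have a transcript at 0. A further 230 coding accessions bear no name in either table, and 117 genes with an accession number within 2 of such an accession of 9 digits were set aside, because a lost isoform would appear as a change. These rules on coverage, summing and unnamed accessions were chosen after seeing the data. Accessions of 6 digits lost from the annotation are not caught by them.

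Replicated groups were compared with limma 3.58.1 in R 4.3.3, as lmFit and eBayes with a trend on log2 of the value plus 1, for genes at 1 or more in at least 2 samples. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design named 11 samples of the 5 replicated groups as sharing the estimate of spread; the fit used 10, because unfused fibroblast replicate 3 holds no human transcript. All errors are SD over 2 samples for levels and SE of the fit for log2 fold changes. The homokaryon sample entered no test and is given as ratios to the mean of unfused fibroblast replicates 1 and 2.

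The test, the filter, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, among called genes in the upper 50 percent of abundance whose replicates did not overlap between groups, the 8 with the largest rise and the 8 with the largest fall for each heterokaryon day against co-culture, and the 5 and 5 for other comparisons. It adds the members of the pluripotency and IL6 JAK STAT lists and up to 4 members with the smallest adjusted p per described list. For the homokaryon sample, genes are named from the 5 highest and 5 lowest ratios among the more abundant genes (upper 25 percent). Genes named outside the rule are said to be so.

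The 28 gene lists cover pluripotency, IL6 JAK STAT, fibroblast matrix, mesenchymal regulators, epithelial, neural, endoderm and mesoderm, endothelial, haematopoietic, keratinocyte, smooth muscle contractile, cell cycle, histones, DNA methylation, chromatin regulators, p53 and senescence, interferon response, inflammatory NFkB, immediate early, TGF beta targets, heat shock, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, lysosome and autophagy, oxidative phosphorylation, ribosomal proteins and conserved abundant genes. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation, and fry, were run on genes covered by all libraries they used. For the heterokaryon days they left out the unfused fibroblasts, so they had fewer libraries than the preset test and in part fewer genes. For cell cycle at day 1 they used 11 of 20 members, with an estimated correlation of -0.083. A call lost there thus does not by itself show that correlation between genes ended it. Ribosomal proteins kept all 17 members at day 1, with an estimated correlation of 0.638 against the preset 0.01. In co-culture against unfused fibroblasts they kept all 12 members, with an estimated correlation of 0.573. The loss of these 2 calls thus goes with a correlation far above the preset. For the homokaryon sample, a list's median was placed among 10000 random lists matched on abundance.

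The procedure was tested on simulated data with 200 changed genes per comparison. For day 1 against co-culture it recovered 2.99% of 2-fold, 55.2% of 4-fold and 78.8% of 8-fold changes and called 6 of 3364 unchanged genes, so smaller changes are mostly missed at this sample number. A list raised by 1 on the log2 scale was found in each of the 4 comparisons of lists, with 0 other lists called. The simulated genes varied independently of each other, so this does not test how often lists of correlated genes are called wrongly.

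Alternatives were quantile normalization, upper quartile scaling, no filter, limma without trend, a pseudocount of 0.1, only the 2 groups compared, the replicate number as a block, a fold of 2 or more in addition, leaving out 55 genes at least 4-fold higher in co-culture than in unfused fibroblasts, and leaving out each replicate. Single transcripts, genes covered in part, the largest transcript, genes beside an unnamed accession kept, the fit without unfused fibroblasts, and scaling for lists were added after the data were seen. With 1 replicate left out, the lone sample of its group is assumed to vary like the other groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.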

Results

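Human transcript levels were measured by polyA RNA sequencing in 11 usable libraries. They comprise heterokaryons at day 1, day 2 and day 3 after fusion, co-cultures and unfused fibroblasts, with 2 libraries each, and 1 homokaryon library. A heterokaryon is a fused cell that keeps the nuclei of its mouse embryonic stem cell and human fibroblast parents apart. The series examines how the fibroblast genome is reprogrammed over this time course. Levels are called RPKM, a read density per transcript length and library, although the unit is inferred.

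Read totals were not given, and no interval that needs them is printed. Value times transcript length clustered loosely near multiples of a step, the best of many candidates, which was not tested against values without a step. The step is inverse to depth if 1 step is 1 read, and is known only to within a whole factor. On this scale the depth of heterokaryon replicates 1 and 2 was 3.68 and 1 at day 1, 1.81 and 1.65 at day 2, and 1.29 and 2.08 at day 3. It was 1.18 and 1.23 in co-culture, 7.97 and 6.79 in unfused fibroblasts and 4.60 in the homokaryon library. If these steps hold, the mixed libraries resolved low human values less finely than the purely human ones. The tables end at different accessions, so 4801 genes were covered for day 1 against co-culture, 3420 for day 2, 4103 for day 3 and 1532 where unfused fibroblasts were compared. Counts of genes are therefore counts within a part of the genes and are not comparable between comparisons. Across genes, log2 values of the replicates correlated at 0.867 at day 1, 0.925 at day 2, 0.883 at day 3, 0.938 in co-culture and 0.990 in unfused fibroblasts; genes are not independent replicates.

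POU5F1, the pluripotency factor OCT4, was followed as the sum of its transcripts covered in every mixed library. It stood at 26.9 and 27.4 at day 1, 56.9 and 48.6 at day 2, and 27.3 and 18.7 at day 3, against 0 and 0.0847 in co-culture, 0.543 in unfused fibroblast replicate 2 and 0.928 in the homokaryon library. Co-culture also holds mouse stem cells, unfused. This sum, and a fit that included genes covered in part, were chosen after the data were seen. In that fit POU5F1 rose at day 1 (log2 fold change 4.76, SE 0.42, adjusted p = 0.0047), day 2 (5.69, SE 0.41, adjusted p = 0.00162) and day 3 (4.50, SE 0.42, adjusted p = 0.00512). No POU5F1 difference between days was called: day 2 against day 1 gave 0.93 (adjusted p = 0.343) and day 3 against day 2 gave -1.19 (adjusted p = 0.585). This does not show equal levels. A further POU5F1 accession lies past the end of the tables, and the adjusted p reached 0.0505 at day 1 without co-culture replicate 1 and 0.05004 at day 3 without co-culture replicate 2. SOX2 was listed in none of the libraries. It lies within the covered part of every mixed library, so the coverage rule takes it as 0 there. NANOG, LIN28A and SALL4 lie past the covered part and were not analysed here.

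**Figure D1:**
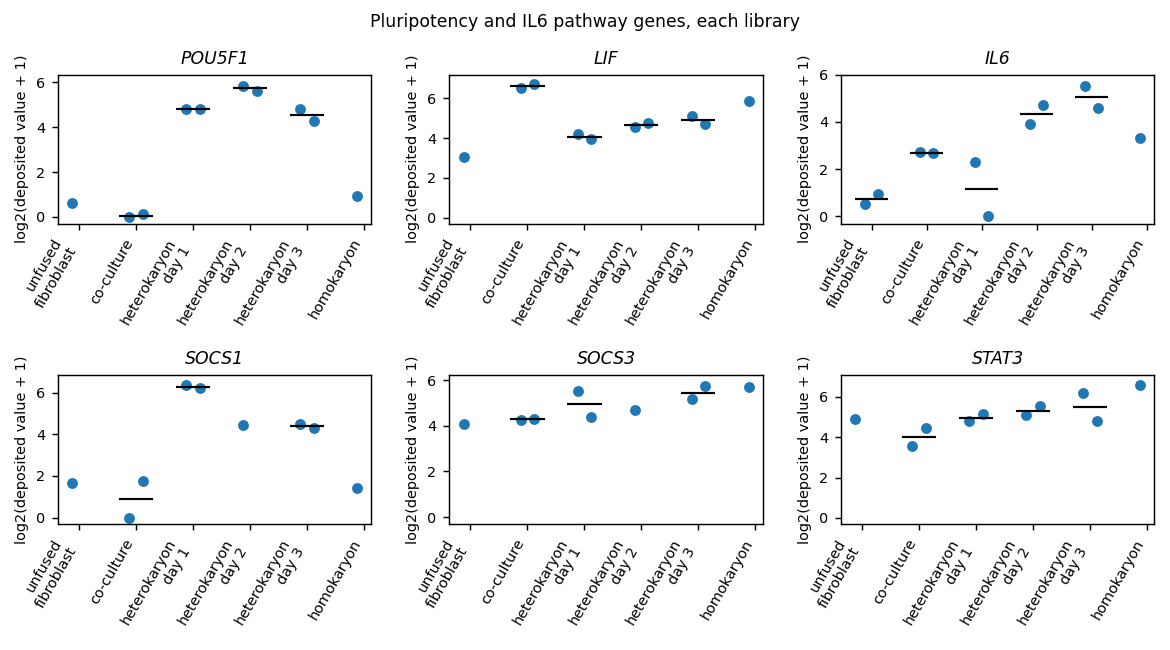
Levels of POU5F1, LIF, IL6, SOCS1, SOCS3 and STAT3 in each library, as log2 of the value plus 1, by group; points are libraries and horizontal lines are means of the log2 values where a group has 2 covered libraries. POU5F1 lies between 18.7 and 56.9 in the 6 heterokaryon libraries and at 0.0847 or less in co-culture.

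Of 16 measured IL6 JAK STAT genes, SOCS1 and PIM3 rose and LIF and IL11 fell at day 1 (5 called when adjusted over the list alone). LIF, the cytokine that sustains mouse stem cells, fell from 96.7 ± 7.97 in co-culture (SD, n = 2) to 15.9 ± 2.24 at day 1, 24.3 ± 2 at day 2 and 29 ± 5.61 at day 3. The log2 fold changes of LIF were -2.54, -1.95 and -1.71 (adjusted p = 0.00434, 0.00862 and 0.0287). In unfused fibroblast replicate 2 LIF was at 7.36, below all 6 heterokaryon libraries, and in the homokaryon library at 56.9; LIF was not tested in co-culture against fibroblasts. The cytokine IL11 fell from 27.1 ± 1.49 to 2.91 ± 3.80 at day 1 (-3.31, adjusted p = 0.0359) and the kinase PIM3 rose from 8.19 ± 4.34 to 38.2 ± 7.88 (2.17, adjusted p = 0.0428). Neither was called at day 2 or day 3. SOCS1, a feedback inhibitor of JAK signalling, rose from 1.22 ± 1.72 to 77.1 ± 5.65 at day 1 and 20 ± 1.99 at day 3, and was not covered at day 2. IL6 itself was at 5.47 ± 0.151 in co-culture, 2 ± 2.83 at day 1, 19.8 ± 7.82 at day 2 and 33.7 ± 15.0 at day 3, with adjusted p = 0.229, 0.21 and 0.127. It passed as lower at day 1 without heterokaryon day 1 replicate 1 (adjusted p = 0.0386) and as higher at day 2 in a fit of only the 2 groups (adjusted p = 0.044). The kinase PIM1 stood at 10.3 ± 6.87 in co-culture and at 51.4 ± 1.25, 47.0 ± 4.83 and 94.2 ± 90.4 on the 3 days (adjusted p = 0.0786, 0.0941 and 0.0828). SOCS3 did not pass at day 1 (32.3 ± 17.4 against 18.7 ± 0.380, adjusted p = 0.416) or day 3 (43.7 ± 12.5, adjusted p = 0.245). The covered transcripts of STAT3 summed to 15.9 ± 7.11 in co-culture and 30.7 ± 5.16, 39.3 ± 9.12 and 50 ± 32.5 on the 3 days (adjusted p = 0.387, 0.257 and 0.278). The LIF calls ended without either co-culture replicate on each day (largest adjusted p = 0.057, 0.0969 and 0.216), at day 2 also without either day 2 replicate, and at day 3 also without day 3 replicate 2 and in the fit with genes covered in part (adjusted p = 0.0649). The SOCS1 call held at day 1 each time. At day 3 it held without co-culture replicate 2, and ended without each other library and with genes covered in part (adjusted p = 0.0777). At day 1 the IL11 call held only without day 1 replicate 1 (largest adjusted p = 0.192) and the PIM3 call ended whichever library was left out (0.249); with genes covered in part they had 0.0522 and 0.0771, and PIM3 had 0.0542 with quantile normalization.

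Day 1 against co-culture asks which human genes differ soon after fusion. CCL5, a chemokine that attracts leukocytes, rose from 0.274 ± 0.261 to 139 ± 5.57 (SD, n = 2; log2 fold change 6.79, SE 0.52, adjusted p = 0.00126), with 6.26 in unfused fibroblast replicate 2 and 17.3 in the homokaryon library. ISG15, an interferon-induced ubiquitin-like protein, rose from 10.1 ± 2.18 to 368 ± 147 (5.01, SE 0.38, adjusted p = 0.00253). CKS2, a cofactor of cyclin-dependent kinases, rose from 3.79 ± 4.33 to 128 ± 29.2 (41.9 in unfused fibroblast replicate 2), and TROAP, a spindle protein, from 1.23 ± 1.51 to 59.2 ± 15.5. The LIM protein CRIP1 (52.4 ± 13.1 against 0.493 ± 0.697), the antiviral membrane protein BST2 (53.8 ± 1.5 against 1.66 ± 2.35) and the phosphodiesterase PDE4C (33.0-fold) completed the 8 largest rises with SOCS1. TNFRSF11B, the decoy receptor osteoprotegerin, fell from 57.0 ± 1.70 to 0.109 ± 0.154 (log2 fold change -5.71, SE 0.74, adjusted p = 0.00474). WNT5A, a Wnt ligand, fell from 41.3 ± 4.23 to 1.57 ± 1.55, and AREG, a ligand of the EGF receptor, from 264 ± 45.9 to 19.4 ± 0.144, where unfused fibroblast replicate 2 had 3.23. STC1, a secreted hormone, fell from 520 ± 4.94 to 36.3 ± 8.94 and the bradykinin receptor BDKRB1 from 77.7 ± 7.90 to 4.95 ± 0.232. The transcription factor SALL1 (1.72 ± 2.44 against 50.8 ± 6.91), the transporter SLC16A6 (30.7-fold lower) and C2orf81 (0 and 15.0 against 68.7 and 58.9) were also among the 8 largest falls. Several of these genes were lower in unfused fibroblasts than in co-culture too: C2orf81 was at 1.98 and 4.42, and in replicate 2 SALL1 was at 10.1, WNT5A at 12.9, TNFRSF11B at 29.2 and STC1 at 106.

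Across day 1 against co-culture, 396 of 3564 tested genes were called with limma, 231 higher and 165 lower, and 977 had an unadjusted p under 0.05. The share higher was 58.3% as deposited, 57.1% after upper quartile scaling and 49.9% after quantile normalization. Of the 16 genes named by the rule, CCL5, SOCS1, CRIP1, CKS2, ISG15, PDE4C and BDKRB1 passed with each library left out in turn. The count was 43 without co-culture replicate 1 and 48 without co-culture replicate 2, where 9 and 7 of the 16 passed, and 14 passed without day 1 replicate 1.

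Of 20 measured cell cycle genes, 13 rose at day 1 and none fell, with a median log2 fold change of 2.96 (camera adjusted p = 5.99e-13; adjusted p = 0.121 with an estimated correlation; 15 called when adjusted over the list alone). TOP2A, a topoisomerase of dividing cells, rose from 1.60 ± 0.162 to 37.5 ± 9.40, and the transcription factor MYBL2 from 0.382 ± 0.541 to 23.9 ± 1.01. CENPA, the centromeric histone, stood at 15.3 and 13.0 and CCNA2, cyclin A2, at 23.2 and 14.4, and both were unlisted in co-culture and taken as 0. Unfused fibroblast replicate 2 lay between these levels, with MYBL2 at 13.9, CENPA at 4.84, CCNA2 at 3.53 and TOP2A at 8.54, so the rise is measured from co-culture levels below it. Of 12 interferon response genes, ISG15, BST2 and MX2 rose (camera adjusted p = 8.54e-05; adjusted p = 0.321 with an estimated correlation; 7 called when adjusted over the list alone). The homokaryon library, fused without mouse cells, had ISG15 at 149, BST2 at 105 and MX2 at 22.6, the latter 2 above both day 1 libraries. In the p53 and senescence list, the stress cytokine GDF15 rose from 63.4 ± 17.6 to 878 ± 169. The repair genes XPC (4.16-fold) and DDB2 (2.75-fold) rose with it, and IGFBP3 fell 3.64-fold, of 5 measured (camera adjusted p = 0.00153; 4 called when adjusted over the list alone). TOP2A, MYBL2, ISG15 and GDF15 passed with each library left out, and the other calls in these 3 lists did not: the largest adjusted p was 0.0601 for CENPA and 0.0607 for CCNA2 without a co-culture replicate, 0.0507 for BST2 without co-culture replicate 2, 0.234 for MX2, 0.106 for XPC, 0.137 for DDB2 and 0.257 for IGFBP3. Quantile normalization ended the calls of MX2 and DDB2 (adjusted p = 0.0576 each).

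PODXL, a sialomucin of stem cells and podocytes, rose from 9.22 ± 2.58 to 144 ± 10.1 and was the 1 of 5 measured pluripotency genes to pass (camera adjusted p = 0.0185; 2 called when adjusted over the list alone). Measured genes are those that passed the filter on low values. LIN28B, DPPA5, UTF1 and LEFTY2 were covered in every mixed library but did not pass it, so the list test leaves them out. Their means were 0 in co-culture and 0, 0, 0 and 0.344 at day 1. Among 10 histones, H3-3B and H2AZ1 rose by 2.13 and 1.48 on the log2 scale and H2BC21 fell by 2.68 (camera adjusted p = 0.0185 upward; adjusted p = 0.762 with an estimated correlation; 5 called when adjusted over the list alone). The histone median of -6.0e-05 and mean of 0.36 differed in sign. RPL27 rose 1.68-fold, 1 of 17 ribosomal proteins, with a list median of 0.48 (camera adjusted p = 0.0218; adjusted p = 0.584 with an estimated correlation; 0 called when adjusted over the list alone). Among 17 TGF beta targets, the matricellular CCN1 rose and ID2, LTBP2 and TGFBR2 fell (camera adjusted p = 0.0287 downward; adjusted p = 0.394 with an estimated correlation; 5 called when adjusted over the list alone). ID2, an inhibitor of differentiation factors, was unlisted in both day 1 libraries and taken as 0, against 12.9 and 18.4 in co-culture. PODXL passed with each library left out. H3-3B, H2AZ1, H2BC21, RPL27, CCN1, ID2, LTBP2 and TGFBR2 did not, with largest adjusted p from 0.055 for ID2 to 0.245 for RPL27. The correlation of the pluripotency and p53 lists was not estimated, since fewer than 5 members were covered by all libraries of that test. Without day 1 replicate 1 the adjusted p became 0.242 for TGF beta targets, 0.0567 for histones, 0.0712 for pluripotency and 0.321 for ribosomal proteins. Without day 1 replicate 2 it became 0.109 for histones and 0.0699 for pluripotency, and without co-culture replicate 2 it became 0.103, 0.152 and 0.103 for TGF beta targets, histones and ribosomal proteins. Quantile normalization ended the ribosomal list call (adjusted p = 0.521) and those of RPL27 (0.149) and H2BC21 (0.0525), and upper quartile scaling that of RPL27 (0.0561).

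The other 16 lists tested at day 1 did not pass. Adjusted p was 0.0683 for cholesterol synthesis, 0.0749 for oxidative phosphorylation and for epithelial genes, 0.0906 for mesenchymal regulators and 0.0909 for fibroblast matrix. It was 0.206 for DNA methylation, 0.297 for hypoxia and glycolysis and for heat shock, 0.358 for smooth muscle contractile and 0.536 for immediate early and for lysosome and autophagy. It was 0.619 for conserved abundant genes, 0.661 for IL6 JAK STAT, 0.769 for inflammatory NFkB, 0.782 for chromatin regulators and 0.893 for unfolded protein response. The median, mean or test differed in sign for hypoxia and glycolysis, immediate early, lysosome and autophagy, IL6 JAK STAT and unfolded protein response. Among lists too small to test, 1 of 4 keratinocyte genes rose, and none of 2 endoderm and mesoderm, 3 endothelial and 3 haematopoietic genes was called; no neural gene was measured.

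**Figure D2:**
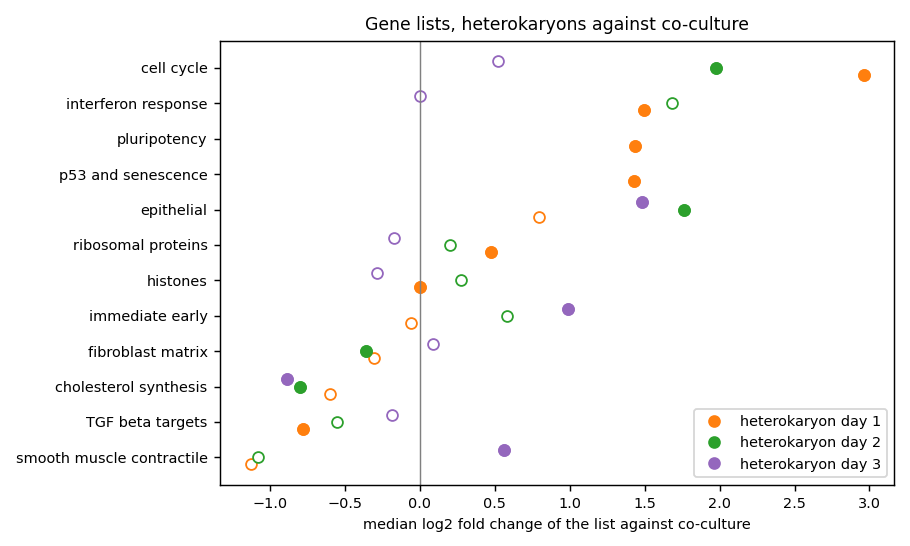
Median log2 fold change against co-culture of each gene list called on at least 1 day, by list, with 1 colour per day; filled points passed camera at the preset correlation and open points did not. Cell cycle genes have a median of 2.96 at day 1 and 0.52 at day 3.

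Day 2 against co-culture asks the same a day later. KHDC1L, a gene of the preimplantation embryo, rose from 0.361 ± 0.511 to 131 ± 9.61 (SD, n = 2; log2 fold change 6.65, SE 0.96, adjusted p = 0.00485). KRT19, an epithelial keratin, rose from 6.11 ± 0.243 to 294 ± 50.1 (5.36, SE 0.33, adjusted p = 0.00027) and DES, the muscle filament desmin, from 0.486 ± 0.688 to 52.5 ± 3.74. Complement C3 rose from 0.501 ± 0.708 to 43.7 ± 1.04 and the antioxidant enzyme GPX3 from 4.21 ± 1.08 to 159 ± 21.6. In the homokaryon library C3 was at 39.3, GPX3 at 11.2, KRT19 at 3.18 and DES at 0. CRIP1 (122 ± 11.4 against 0.493 ± 0.697), the lysosomal fucosidase FUCA1 (44.5 ± 9.78 against 0.408 ± 0.577) and CCL5 (36 ± 18.2 against 0.274 ± 0.261) were the other large rises. SFRP1, a secreted Wnt antagonist, fell from 724 ± 27.8 to 87.8 ± 26.2 (log2 fold change -3.06, SE 0.33, adjusted p = 0.00291). The collagenase MMP1 fell from 333 ± 52.5 to 43.8 ± 20.7 and the pentraxin NPTX1 from 224 ± 5.23 to 24.1 ± 2.44. AREG (10.5-fold lower), STC1 (9.49-fold lower), the microfibril protein MFAP4 (9.62-fold lower) and UROD, a haem synthesis enzyme at 0 and 18.1 against 67.7 and 82.1, also fell, as did MVK. Unfused fibroblast replicate 2 had SFRP1 at 494.5, MMP1 at 199, NPTX1 at 40.2 and MFAP4 at 75.4.

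Across day 2 against co-culture, limma called 258 of 2427 genes, 164 higher and 94 lower, with 623 at an unadjusted p under 0.05. The share higher was 63.6% as deposited and 46.2% after quantile normalization, and the median of all genes was 0.30 as deposited, 0.24 after upper quartile scaling and 0.01 after quantile normalization. Left-out libraries gave 30 and 28 genes without day 2 replicates 1 and 2, and 46 and 36 without co-culture replicates 1 and 2; of the 16 named genes 9, 10, 10 and 8 passed. C3, CCL5, CRIP1, DES, GPX3, KRT19, NPTX1 and SFRP1 passed each time.

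Among cholesterol synthesis enzymes at day 2, MVK fell from 19.3 ± 2.82 to 1.67 ± 0.885, DHCR7 from 148 ± 14.5 to 42.6 ± 0.292 and MVD from 29.7 ± 4.84 to 6.87 ± 1.29, and 6 of the 9 measured enzymes did not pass (camera adjusted p = 0.000793; adjusted p = 0.182 with an estimated correlation; 4 called when adjusted over the list alone). Unfused fibroblasts lay between these levels, with MVK at 7.49 and 6.71, and in replicate 2 DHCR7 at 59.8 and MVD at 10.7. The 3 list members measured in co-culture against fibroblasts were higher in co-culture (median log2 fold change 1.31), too few to test. The fall is thus measured from co-culture levels above those of fibroblasts. Of 11 cell cycle genes, MYBL2, CENPA, TOP2A and CCNA2 rose (camera adjusted p = 0.000793; adjusted p = 0.182 with an estimated correlation; 6 called when adjusted over the list alone). TOP2A stood at 13.6 ± 2.63 and MYBL2 at 21.2 ± 1.2. Of 7 epithelial genes, KRT19 and the tight junction protein CLDN4 rose, the latter from 0.8 ± 1.13 to 26.4 ± 8.25 (camera adjusted p = 0.000951; adjusted p = 0.318 with an estimated correlation; 2 called when adjusted over the list alone). Of 19 fibroblast matrix genes, the collagens COL5A1 and COL3A1, the receptor PDGFRB and the protease inhibitor TIMP1 fell and TIMP3 rose (camera adjusted p = 0.0188 downward; adjusted p = 0.437 with an estimated correlation; 6 called when adjusted over the list alone). The fibroblast matrix call ended with quantile normalization (adjusted p = 0.135), without day 2 replicate 1 (0.0712) and without co-culture replicate 2 (0.0600). MYBL2 and KRT19 passed with each library left out; CLDN4 lost its call without either day 2 replicate (largest adjusted p = 0.0676). MVK, DHCR7, MVD, CENPA, TOP2A, CCNA2, COL5A1, COL3A1, PDGFRB, TIMP1 and TIMP3 lost it whichever of the 4 libraries was left out, with largest adjusted p from 0.076 for MVK to 0.221 for PDGFRB. Quantile normalization ended the calls of CCNA2 (adjusted p = 0.0732) and COL3A1 (0.0579).

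Outside the called lists at day 2, the heat shock protein CRYAB rose from 48.9 ± 1.81 to 437 ± 109 and the stress factor ATF3 from 12.9 ± 5.10 to 136 ± 0.477; both passed with each library left out. CRIPTO, a coreceptor of Nodal and stem cell marker, stood at 5.89 and 9.49 against 0 and 0.427 and was the 1 of 3 measured pluripotency genes to pass (adjusted p = 0.0421), a call lost whichever library was left out (largest adjusted p = 0.21) and with quantile normalization (0.0766). The other 14 lists tested at day 2 did not pass, with TGF beta targets, hypoxia and glycolysis and mesenchymal regulators nearest at an adjusted p of 0.138. The median, mean or test differed in sign for IL6 JAK STAT, chromatin regulators, histones, ribosomal proteins, lysosome and autophagy and smooth muscle contractile.

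At day 3 many of the same genes stood apart from co-culture. C3 rose from 0.501 ± 0.708 to 70.2 ± 11.7 (SD, n = 2; log2 fold change 5.64, SE 0.54, adjusted p = 0.00176), DES to 46.3 ± 13.5, KRT19 to 182 ± 54.6 and GPX3 to 102 ± 4.03. CRIP1 (63.7 ± 16.3), CCL5 (32.2 ± 17.7), KHDC1L (15.1 and 107 against 0.722 and 0) and RRAD, a small GTPase of muscle (18.8-fold), completed the 8 largest rises. AREG fell from 264 ± 45.9 to 12.5 ± 12.9 (log2 fold change -4.72, SE 0.66, adjusted p = 0.0118). HGF, hepatocyte growth factor, fell from 162 ± 50.3 to 18.6 ± 10.3, MMP1 to 38.9 ± 12.2, SFRP1 to 105 ± 33.5 and NPTX1 to 28.1 ± 0.00516. SLC16A6 (14.2-fold lower), TRNP1, a nuclear protein of neural progenitors (6.18-fold lower), and MFAP4 (4.90-fold lower) also fell. Unfused fibroblast replicates 1 and 2 had HGF at 22.5 and 22.8, so its fall is measured from co-culture levels above theirs. TRNP1 stood at 127 and 126 in them, above co-culture.

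Limma called 107 of 2996 genes at day 3, 70 higher and 37 lower, with 545 at an unadjusted p under 0.05. The share higher was 65.4% as deposited, 67% after upper quartile scaling and 57.4% after quantile normalization. The count was 5 without co-culture replicate 1, 14 without co-culture replicate 2, 164 without day 3 replicate 1 and 62 without day 3 replicate 2, and 5, 7, 15 and 14 of the 16 named genes passed. C3, CRIP1, DES, GPX3 and KRT19 passed each time.

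KRT19 was the 1 of 9 epithelial genes to pass at day 3, with a list median of 1.48 (camera adjusted p = 0.000929; adjusted p = 0.214 with an estimated correlation; 6 called when adjusted over the list alone). Cholesterol synthesis had a median of -0.89 with none of 12 genes called over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.00159; adjusted p = 0.214 with an estimated correlation). As at day 2, this is measured from co-culture, where the members measured against fibroblasts were higher. Of 11 immediate early genes, ATF3 rose from 12.9 ± 5.10 to 100 ± 0.559 (camera adjusted p = 0.00176; adjusted p = 0.214 with an estimated correlation; 4 called when adjusted over the list alone). In the smooth muscle contractile list DES and the actin ACTA2, from 70.0 ± 5.56 to 287 ± 121, rose of 7 measured (camera adjusted p = 0.00778; adjusted p = 0.634 with an estimated correlation; 2 called when adjusted over the list alone). The smooth muscle call ended without day 3 replicate 1 (median -0.08, adjusted p = 0.48) and the immediate early call without day 3 replicate 2 (adjusted p = 0.0754). ATF3 did not pass without co-culture replicate 1 (adjusted p = 0.0855), nor ACTA2 without either co-culture replicate (largest adjusted p = 0.152). KLF4, a reprogramming factor, rose from 0.506 ± 0.715 to 12.6 ± 4.85 (adjusted p = 0.0385), a call lost whichever library was left out (largest adjusted p = 0.223). The other 15 lists tested at day 3 did not pass; hypoxia and glycolysis came nearest (adjusted p = 0.050006) and cell cycle had 0.407. The median, mean or test differed in sign for heat shock, TGF beta targets, lysosome and autophagy, chromatin regulators, unfolded protein response and fibroblast matrix.

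The days shared many of their changed genes. Of 2427 genes tested on all days, 40 were higher and 21 lower than co-culture on each, among them CCL5, C3, CRIP1, DES, KRT19, GPX3, PDE4C and MYBL2 (higher) and AREG, LIF, HGF, SFRP1, NPTX1 and BDKRB1 (lower). Of the lower genes named here, all but BDKRB1 were also lower in unfused fibroblast replicate 2 than in co-culture, with HGF at 22.8. Day 1 and day 2 shared 95 higher genes, where 11 are expected if the calls of the 2 days were independent. They shared 53 lower genes, where 4.92 are expected on that basis. No gene went opposite ways. The log2 fold changes correlated at 0.686 between day 1 and day 2, 0.636 between day 1 and day 3 and 0.796 between day 2 and day 3, across genes. Since all days share the 2 co-culture libraries, values simulated with no difference correlated at 0.502, 0.503 and 0.501, and at most 1 gene was called on both days of a pair in 30 simulations. With no change simulated, this does not give how many shared calls the common co-culture libraries add where many genes differ.

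**Figure D3:**
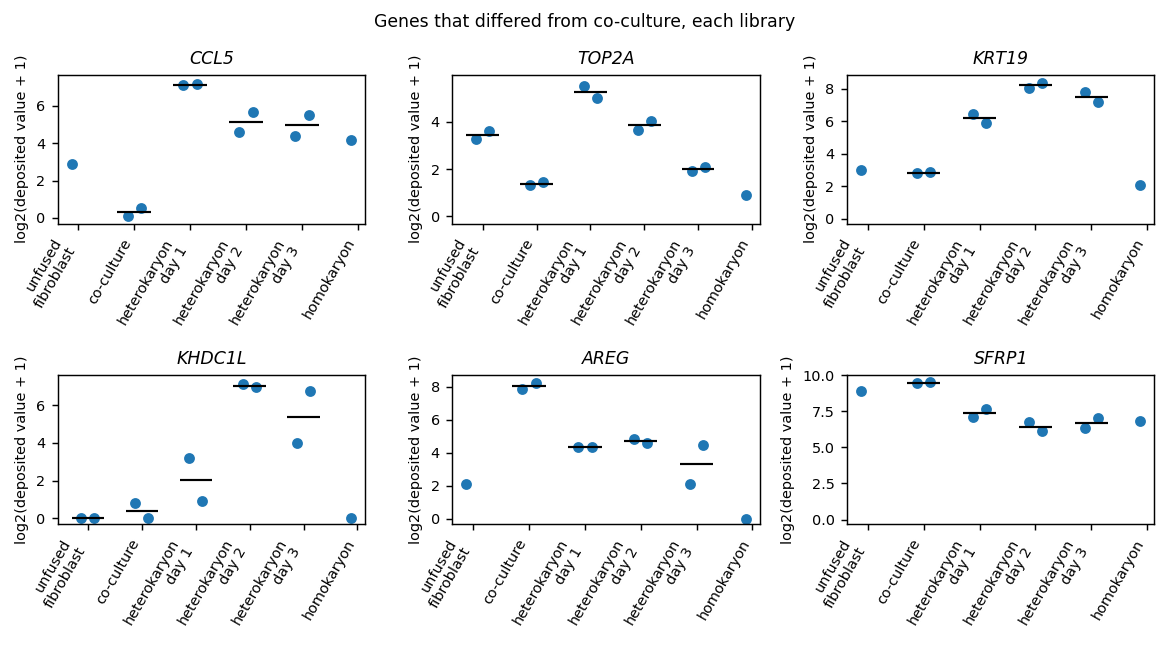
Levels of CCL5, TOP2A, KRT19, KHDC1L, AREG and SFRP1 in each library, as log2 of the value plus 1, by group; points are libraries and horizontal lines are means of the log2 values where a group has 2 covered libraries. TOP2A has means of 37.5, 13.6 and 3.03 at day 1, day 2 and day 3 and 1.60 in co-culture.

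Day 3 against day 1 asks which genes changed over the course. TOP2A fell from 37.5 ± 9.40 to 3.03 ± 0.328 (SD, n = 2; log2 fold change -3.23, SE 0.43, adjusted p = 0.0348) and the mitotic kinase AURKB from 70.7 ± 44.6 to 1.87 ± 2.64 (-4.89, SE 0.82, adjusted p = 0.0451). PTTG1, securin, fell from 460 ± 199 to 37.2 ± 0.260 and the thymidine kinase TK1 from 63.1 ± 1.17 to 6.69 ± 4.90, as did PLAAT4, a retinoid-induced enzyme, from 58.1 ± 9.09 to 1.66 ± 2.35. PTX3, a secreted pentraxin, rose from 6.02 ± 0.282 to 48.0 ± 4.42 (2.80, SE 0.34, adjusted p = 0.0348). The growth factor binding protein IGFBP3 rose from 13.6 ± 6.59 to 95.6 ± 48.8 and tropomyosin TPM1 from 51.7 ± 9.77 to 431 ± 321. The lipid phosphatase PLPP3 (12.3-fold) and SUOX, sulfite oxidase (13.4 ± 0.920 against 0.981 ± 1.39), rose too. Quantile normalization ended the call of SUOX and upper quartile scaling those of AURKB and PTTG1 (adjusted p = 0.0514 each). IL6 rose from 2 ± 2.83 to 33.7 ± 15.0 (3.88, SE 0.75, adjusted p = 0.0451), but not when genes covered in part were added (adjusted p = 0.0674). Of 16 measured cell cycle genes 15 were lower at day 3, 4 passed, and the median was -2.22; the lists were not tested between days. Limma called 38 of 2996 genes, 21 higher and 17 lower, with 552 at an unadjusted p under 0.05. With the replicate number as a block it called 0. The count fell to 0 without day 1 replicate 1, without unfused fibroblasts in the fit, and in a fit of only these 2 groups. It was 33, 39 and 54 without day 1 replicate 2, day 3 replicate 1 and day 3 replicate 2, where 4, 5 and 6 of the 10 named genes passed.

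Day 2 differed from day 1 in 6 of 2427 genes, 5 higher and 1 lower, with 456 at an unadjusted p under 0.05 in limma. A fit with the replicate number as a block called 0. PTX3 rose from 6.02 ± 0.282 to 40.8 ± 13.3 (SD, n = 2; log2 fold change 2.54, adjusted p = 0.0406), DPYSL2, a cytoskeletal regulator, from 24.8 ± 3.51 to 94.4 ± 7.92, and the actin-binding TAGLN2 fell from 615 ± 1.58 to 241 ± 5.67. None of the 3 passed with any 1 library left out. The count was 0 without day 1 replicate 1, 1 without either day 2 replicate and 5 without day 1 replicate 2. It was 2 with upper quartile scaling, both higher, and 0 with quantile normalization, where the median of all genes moved from 0.23 to 0.00. Between day 2 and day 3, limma called 0 of 2427 genes, with 196 at an unadjusted p under 0.05; the count was 18 without day 3 replicate 1 and 2 without day 2 replicate 2, and quantile normalization moved the median of all genes from -0.16 to 0.00.

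Co-culture against unfused fibroblasts asks which human genes differ beside mouse cells without fusion. IL1B, an inflammatory cytokine, rose from 0.0215 ± 0.0304 in fibroblasts to 49.1 ± 2.97 in co-culture (SD, n = 2; log2 fold change 5.62, SE 0.30, adjusted p = 2.91e-05). HGF rose from 22.6 ± 0.231 to 162 ± 50.3 and the adhesion receptor ICAM1 from 6.95 ± 0.411 to 39.9 ± 0.820. COL7A1, an anchoring collagen (3.91-fold), IGFBP5 (3.26-fold) and TIMP3 (3.06-fold) rose as well. TOP2A fell from 9.85 ± 1.85 to 1.60 ± 0.162. Limma called 8 of 961 genes, 6 higher and 2 lower, with 113 at an unadjusted p under 0.05. Only IL1B passed with each library left out; the count was 1 without co-culture replicate 1, co-culture replicate 2 or fibroblast replicate 2. The share higher was 75.0% as deposited, 56.3% with quantile normalization and 100% with upper quartile scaling, which ended the calls of HGF, IGFBP5, TIMP3 and TOP2A (largest adjusted p = 0.0627). Quantile normalization ended that of IGFBP5 (0.139).

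Of 6 inflammatory NFkB genes IL1B and ICAM1 rose in co-culture (camera adjusted p = 4.55e-12; adjusted p = 0.0358 with an estimated correlation; 3 called when adjusted over the list alone). None of 12 ribosomal proteins was called, with a median of 0.45 (camera adjusted p = 0.00152; adjusted p = 0.356 with an estimated correlation; 0 called when adjusted over the list alone), and quantile normalization ended that call (adjusted p = 0.61). Fibroblast matrix (adjusted p = 0.492) and lysosome and autophagy (0.956) did not pass, and their median, mean or test differed in sign. Without fibroblast replicate 1, more genes were covered and 9 lists passed.

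Against unfused fibroblasts, IL1B rose on each day as well: to 46.8 ± 4.47 at day 1, 112 ± 20.7 at day 2 and 82.9 ± 23.2 at day 3, from 0.0215 ± 0.0304 (SD, n = 2; log2 fold change 5.54, 6.77 and 6.33; adjusted p = 3.24e-05, 6.13e-06 and 1.07e-05). PDE4C rose from 0.347 ± 0.0400 to 55.2 ± 3, 55.4 ± 5.87 and 30.2 ± 15.2 on the 3 days, and C3 from 0.107 ± 0.110 to 16.0 ± 9.60, 43.7 ± 1.04 and 70.2 ± 11.7. The homokaryon library, fused without mouse cells, also stood above the fibroblasts, with IL1B at 11.5, PDE4C at 4.23 and C3 at 39.3. COL7A1 (13.4-fold) and the retinoic acid enzyme ALDH1A3 (19.5 ± 6.96 against 0.432 ± 0.105) rose at day 1. KHDC1L and TRIM43B, another gene of the early embryo, were unlisted in the fibroblasts and taken as 0. At day 2 they stood at 138 and 125, and at 37.6 and 45.3. At day 3 they were at 15.1 and 107, and at 8.91 and 41.4. The BMP coreceptor RGMB fell from 72.8 ± 0.384 to 6.69 ± 2.22, 8.74 ± 1.05 and 7.91 ± 1.43. BDKRB1 fell 20.2-fold at day 1 and 7-fold at day 2, TRNP1 12.2-fold at day 1 and 7.47-fold at day 3, GAS6, a ligand of TAM receptors, 8.49-fold at day 2 and 4.60-fold at day 3, and the muscarinic receptor CHRM2 from 20.5 ± 1.68 to 0 and 0.121 at day 2 and to 0.913 ± 0.126 at day 3. GPX8 (2.78 ± 3.69 against 30.9 ± 1.01) and PTRHD1, unlisted and taken as 0 against 16.7 and 19.2, fell at day 1, METRNL (0.769 ± 0.421 against 10.4 ± 2.34) at day 2 and the integrin ITGA6 (4.86-fold lower) at day 3.

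Of 961 genes, limma called 154 at day 1 (90 higher), 120 at day 2 (92 higher) and 70 at day 3 (52 higher) against unfused fibroblasts, with 280, 247 and 220 at an unadjusted p under 0.05. The share higher was 76.7% at day 2 and 74.3% at day 3 as deposited, and 57.3% and 60.3% after quantile normalization, which moved the median of all genes from 0.35 to -0.01 and from 0.15 to -0.06. Without fibroblast replicate 2 the counts were 20, 30 and 14, and without fibroblast replicate 1 they were 77 at day 2 and 41 at day 3; without day 2 replicates 1 and 2, day 2 gave 43 and 52. IL1B, PDE4C, C3 and RGMB passed on each day with each library left out.

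The homokaryon library, which has no replicate, was compared with fibroblast replicates 1 and 2 as ratios without a test. BDKRB2, a bradykinin receptor, stood at 316 against 9.76 ± 0.661 (SD, n = 2), A2M, a protease inhibitor, at 115 against 5.63 ± 0.589, and the collagen COL3A1 at 2251 against 150.3 ± 4.74. The interleukin receptor IL1R1 (11.2-fold) and the mitochondrial enzyme SOD2 (9.56-fold) were also higher. RGMB (7.96-fold), TRNP1 (5.92-fold), C12orf75 (5.25-fold) and SMAGP (5.27-fold) were lower. Of 9 fibroblast matrix genes 8 were higher, with a median log2 ratio of 1.21 that lay at percentile 100 of random lists. Lysosome and autophagy genes had a median of 0.37 (percentile 77.9) and ribosomal proteins 0.26 (percentile 45.8). In all, 198 genes differed at least 2-fold, a number without an error estimate.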

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

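In this part, of the tests, the one for a single wrong file was chosen only after the result was seen. Unfused fibroblast replicate 1 lists 12043 accessions outside the human table and replicate 3 lists 8070, where replicate 2 of the same group lists 28. This is a signal that no comparison of the report uses, and it stands far above replicate 2. Replicate 1 also holds human values that correlate with those of replicate 2 at 0.990 across 684 genes.

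The tables argue against a single wrong file under the label of replicate 3, since 6881 of its accessions are listed by replicate 1 as well. RNA of the kind that the mixed libraries hold cannot be told apart from other sources. Among accessions shared with replicate 1, the median rank correlation over the 8 mixed libraries was 0.6785, with a range from 0.491 to 0.903 over 33 to 73 shared accessions. Libraries without mouse cells had 0.819 (unfused fibroblast replicate 2, 24 shared) and 0.534 (homokaryon, 10 shared). These accessions bear no name in the tables used here, so their organism was not tested, and how they entered the 2 libraries stays open. No biological explanation was tested.

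The difference from co-culture changed between days in tests of the days against each other. It differed in 6 genes between day 2 and day 1 and in 38 genes between day 3 and day 1, where TOP2A fell and PTX3 rose. Without day 1 replicate 1 both counts were 0. At day 2 against day 1 the count was 1 without either day 2 replicate.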

How the results depend on the processing

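In this part, the tests on single transcripts, on genes covered in part, on genes beside an unnamed accession, without unfused fibroblasts in the fit, with scaling for lists, and with replicate 2 as the only homokaryon reference were chosen only after the data were seen. No reported gene reversed direction once called. Over all settings and left-out libraries, 1601 values of named genes kept their side of the threshold, 308 lost it, 2 gained it (IL6 at day 1 and day 2) and 7 values near 0 moved. Where a count moved, the cause was not tested. The files hold no counts, so count-based tests such as DESeq2, edgeR and limma-voom were not run.

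For day 1 against co-culture, 396 genes became 240 without a filter, 222 with only the 2 groups compared, 213 as single transcripts and 43 to 342 over left-out libraries. For day 2, 258 became 522 with only the 2 groups, 111 as single transcripts and 28 to 46 over left-out libraries. For day 3, 107 became 12 with only the 2 groups, 52 as single transcripts and 5 to 164 over left-out libraries. Without 55 genes at least 4-fold higher in co-culture than in fibroblasts, the days gave 378, 245 and 95.

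For co-culture against unfused fibroblasts, 8 became 16 with quantile normalization, 3 with upper quartile scaling, 2 without trend, 14 with a pseudocount of 0.1, 104 with only the 2 groups, 60 as single transcripts, 32 with genes covered in part, 14 with genes beside an unnamed accession and 1 to 11 over left-out libraries. Against unfused fibroblasts, day 1 gave 154, or 300 as single transcripts, 277 with genes covered in part and 20 to 143 over left-out libraries. Day 2 gave 120, or 288 with only the 2 groups and 30 to 77 over left-out libraries, and day 3 gave 70, or 114 with only the 2 groups and 14 to 103.

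Day 2 against day 1 gave 6 genes with limma (456 at an unadjusted p under 0.05), and 0 with quantile normalization, a pseudocount of 0.1, only the 2 groups or no fibroblasts in the fit, 2 with upper quartile scaling, 3 without trend, 19 without a filter, 63 as single transcripts, 57 with genes covered in part and 0 to 5 over left-out libraries. Day 3 against day 2 gave 0 with limma (196 at an unadjusted p under 0.05), 9 without a filter, 2 without trend, 21 as single transcripts, 20 with genes covered in part and 0 to 18 over left-out libraries. Day 3 against day 1 gave 38 with limma (552 at an unadjusted p under 0.05), 19 with upper quartile scaling, 9 without a filter, 1 without trend, 8 with a pseudocount of 0.1, 0 with only the 2 groups or no fibroblasts in the fit, 64 as single transcripts, 63 with genes covered in part and 0 to 54 over left-out libraries.

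Of 7, 4 and 4 lists called on day 1, day 2 and day 3, 0, 0 and 0 were called by camera with an estimated correlation, and left-out libraries gave 3 to 7, 3 to 4 and 3 to 6. Fry called 5, 6 and 5: cell cycle, cholesterol synthesis and epithelial on each day, interferon response and heat shock at day 1 and day 2, immediate early at day 2 and day 3, and hypoxia and glycolysis at day 3. It did not call TGF beta targets, histones and ribosomal proteins at day 1 (adjusted p = 0.0576, 0.25 and 0.159), fibroblast matrix at day 2 (0.164) or smooth muscle contractile at day 3 (0.0935), and was not run for p53 and pluripotency. For these days, fry and camera with an estimated correlation were run without the unfused fibroblasts, on fewer libraries than the preset test. Of 2 lists in co-culture against fibroblasts, 1 was called with an estimated correlation, 1 by fry, 1 with quantile normalization and 2 to 9 over left-out libraries. The homokaryon count of 198 of 636 genes became 150 of 562 and 150 of 558 of the same genes without fibroblast replicates 1 and 2. It became 489 of 1813 over all genes that replicate 2 covers, with replicate 2 as the only reference.

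Replicate numbers are shared between groups, but of 10 pairs of groups the correlation of replicate differences ran from -0.116 to 0.103, so the numbers do not pair the samples. With the replicate number as a block, the days gave 325, 198 and 69 against co-culture and 134, 108 and 61 against fibroblasts; co-culture against fibroblasts gave 4, and day 2 against day 1, day 3 against day 2 and day 3 against day 1 gave 0 each. The block left 7, 4, 4 and 2 lists.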

Other observations

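Of the tests in this part, those on mouse reads, on near-identical copies and on the ends of the tables were chosen only after the result was seen. Genes of the human cleavage stage embryo stood out in heterokaryons at day 2, and were chosen here after their values were seen. TRIM43B stood at 37.6 and 45.3, RFPL4B at 24.1 and 26.1, RFPL4A at 13.7 and 23.9, KDM4E, a histone demethylase, at 7.43 and 8.46, and LEUTX, a homeobox factor of the early embryo, at 14.5 and 6.80. These 5 genes were unlisted in both co-culture libraries and taken as 0. The other days varied by gene. LEUTX was unlisted in both day 1 libraries and in day 3 replicate 1, where it was taken as 0, and was at 0.382 in day 3 replicate 2. RFPL4B was at 2.45 and 5.66 at day 1 and at 5.39 and 14.9 at day 3, and was called higher than co-culture on each day. RFPL4A was at 4.92 and 16.6 at day 3. KHDC1L was at 8.21 and 0.854 at day 1.

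Mouse reads counted on human genes stay open: the mean of 10 such genes in co-culture, which holds mouse stem cells, was 0.1353% of that at day 2, but the genes were picked for this difference, and mouse copies active only after fusion would not show there. Reads shared between near-identical copies cannot be told apart from separate expression for 9 of the 10, because only 1, LEUTX, has no other symbol of the same stem. The stem is the run of letters that opens a symbol. A shared stem does not by itself show a near-identical copy, and sequence similarity was not measured. A wider programme of cleavage stage genes may be active: of 16 further members at 0 in co-culture, 5 were higher in both day 2 libraries (31.2% against 9.41% of 2231 such genes), at percentile 99.3 of 10000 random draws. All 5, among them PRAMEF4 and TRIM64B, share a stem with genes seen before, so shared reads stay open for them too. The draws treat genes as independent, which members of a stem need not be: TRIM64 and TRIM64B both stood at 0.7465 in day 2 replicate 2. The percentile thus cannot tell a wider programme from shared reads.

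The tables end early. Exactly 10000 distinct values are held by 11 of the 12 tables, and an export that keeps this number is a candidate explanation. The tables argue against the view that transcripts past the end were not expressed: before the end 75.5% to 95% of transcripts expressed in the farthest reaching heterokaryon library were listed, and past it 3% at most. The end is the last new value, so a low share past it is in part set by that rule. The rule does not set that 200 more transcripts expressed in that heterokaryon library follow each end compared. No biological explanation was tested.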
